A study of Rattus norvegicus with 20 samples.

How the data were processed

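RNA from the rear-leg skeletal muscle of rats was measured on 20 one-colour Affymetrix expression arrays, 1 per sample, in 4 groups of 5: normal, diabetic, diabetic treated with vanadyl sulfate, and normal treated with vanadyl sulfate. Per the labels' protocols, total RNA was prepared from about 100 mg of muscle kept in a stabilising solution, poly(A) RNA was isolated from it, and biotin-labelled cRNA was made for hybridisation. How diabetes was produced, which leg muscle was taken, and the dose and length of treatment are not given in the sources used here.

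The deposited table holds 1 signal intensity per probe set and array, made by the authors with MAS5 per the submitters' processing notes; its version is not given in the sources used here. The values were on a linear scale. The mean signal after trimming 2% at each end lay between 2503.4 and 2506.46 in the 20 arrays (a 1.00-fold range), so the authors' scaling was kept and no further normalization was applied. The table gives no detection calls, so dim probe sets were judged by their rank within the array. The 5 arrays per group and the spread between them set the precision of each value.

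Of 8799 probe sets, the 59 spike-in and control probe sets were left out of the tests. A probe set was tested when its signal lay above the array's own 40th percentile in at least 5 of the 20 arrays, which left 6027 (69.0%). The values analysed were log2(signal + 16). The platform annotation paired 7018 probe sets with 1 gene symbol, 308 with several and did not list 1473; among the tested ones these were 4940, 246 and 841. Symbols were looked up again through the gene identifiers in the reference annotation, where 6994 were found and 0 changed. A gene was named only from a probe set with 1 symbol, and the probe set with the highest mean signal stood for a gene with several, which gave 3582 tested genes. No genome build is stated for these arrays, so no coordinates are given.

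Group means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) to all 20 arrays, which share 1 estimate of the spread per probe set. The 5 comparisons were diabetic against normal, diabetic treated against diabetic, normal treated against normal, diabetic treated against normal, and the interaction, which is the treatment difference in diabetic rats minus that in normal rats. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 6027 probe sets, with a threshold of 0.05. Adjusted p-values of genes come from limma throughout.

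Gene lists were tested with limma's camera on 1 probe set per gene with a preset correlation between genes of 0.01, which asks whether a list moved more than the other genes, and adjusted over 22 lists and 5 comparisons (110 tests). On simulated data with no effect, 24.9% of list tests with the preset correlation had an unadjusted p under 0.05, against 5.85% with an estimated correlation, so the value with an estimated correlation is printed beside each list that passed with the preset one. The fry test was also run; it asks whether the genes of a list move on balance in 1 direction and does not set them against other genes. The lists were fatty acid uptake and oxidation, PPAR-linked fasting genes, glycolysis and glycogen, tricarboxylic acid cycle and pyruvate entry, oxidative phosphorylation, ubiquitin and proteasome, ribosomal proteins, slow fibre and fast fibre contractile genes, extracellular matrix, heat shock and chaperones, antioxidant and metal response, insulin and IGF signalling, lipid and cholesterol synthesis, neuromuscular junction and denervation, and markers of adipocytes, blood cells, immune cells, endothelium, smooth muscle, nerve and Schwann cells, and mast cells. A list score per array is the mean over the list's genes of the difference from the mean of the normal group.

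The groups, the comparisons, the filter, the gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 risen and 12 fallen genes with the largest change between diabetic and normal muscle, 10 and 10 for diabetic treated against diabetic, and 5 and 5 for each other comparison; where fewer than 3 genes passed, the 5 with the smallest p were given as values. It added the 2 to 4 members of each list described with the smallest p, up to 10 genes that moved back with treatment, and a set of muscle fuel and insulin genes (Pdk4, Ucp3, Slc2a4, Hk2, Cpt1b, Cpt1a, Lpl, Cd36, Fabp3, Insr, Irs1, Scd and Actb; Gapdh and Mb were on the list and had no testable probe set, and 1 further gene of the set is not reported). Any other gene or probe set is marked as chosen after its values were seen.

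RNA quality was read from the control probe sets for Gapdh and beta-actin as the log2 ratio of 3' to 5' signal. Group differences in these ratios were tested with exact permutation tests. The scripts were tested on simulated data with 200 of 6027 probe sets changed: for diabetic against normal, 27.5% of 2-fold and 79.3% of 4-fold changes were recovered, and 5.04% of the calls were false. The noise in this test was drawn independently for each probe set. These shares need not hold in the real arrays, where probe sets varied together. Alternatives covered the pseudocount, the filter, quantile normalization and median centring, the arrays in the fit, the moderation of the spread, array weights, a block for the replicate number, each array left out in turn and the list test. After the data were seen, a larger pseudocount, the 3'/5' ratios as covariates, and fits without 3 arrays of high 3'/5' ratio or without diabetic replicates 1 and 3 were added.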

Results

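Expression was measured in rear-leg muscle of normal and diabetic rats, each untreated or given vanadyl sulfate, a vanadium salt with insulin-like actions, with 5 arrays in each of the 4 groups. The median signal per array lay between 377 and 648, and 6027 probe sets were tested. Nothing in the labels says that the replicates came from separate animals, so each p-value measures the spread between these samples. The correlation between arrays over all tested probe sets ran from 0.683 to 0.968; the highest was between diabetic replicates 1 and 3.

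RNA quality differed among arrays of the same group. The Gapdh log2 ratio of 3' to 5' signal was 2.90 in normal replicate 1, 2.91 in normal replicate 3 and 3.94 in treated diabetic replicate 1, and at most 1.31 in the other 17 arrays. This ratio ran from 0.025 to 2.91 in normal, 0.21 to 1.11 in diabetic, 0.13 to 3.94 in treated diabetic and -0.0038 to 0.68 in treated normal muscle (n = 5 each). For beta-actin the group means were 1.30 ± 1.07, 1.75 ± 0.73, 1.97 ± 0.59 and 1.07 ± 0.68 in the same order (SD, n = 5 each). Over 8 exact permutation tests of group differences, p ran from 0.238 to 0.929 (adjusted p from 0.711 to 0.929). The first principal component, which held 28.3% of the variance, followed the beta-actin ratio over the 20 arrays (Pearson r = -0.83, Spearman rho = -0.85, each with a permutation p of 1e-05, the smallest that the resamples can give, with 1 relation tested by permutation). Its Pearson r with the Gapdh ratio was -0.67, which was not tested. Neither relation was fixed before the data were examined. The correlation with the beta-actin ratio was -0.82 without the 2 arrays farthest from the median ratio and -0.78 after the group means were removed.

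**Figure D1:**
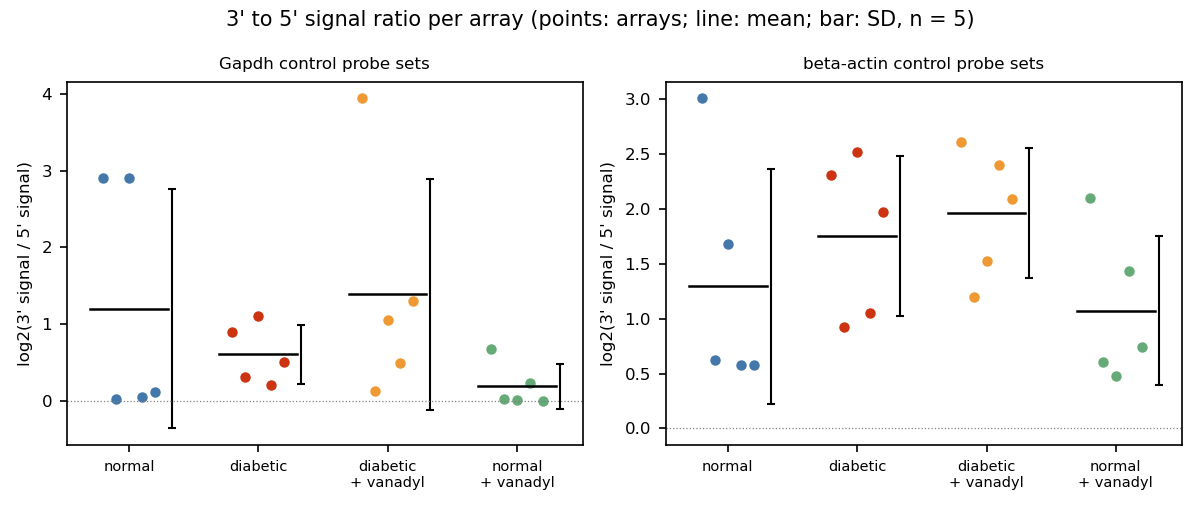
The log2 ratio of 3' to 5' signal of the Gapdh (left) and beta-actin (right) control probe sets in each array, by group; points are arrays, lines are means and bars are SD (n = 5). In the Gapdh panel, normal replicates 1 and 3 and treated diabetic replicate 1 lie at 2.90 or above and the other 17 arrays at 1.31 or below.

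Diabetic against normal muscle asks what diabetes changed in untreated rats. The mechanical stress-responsive muscle protein Ankrd1 (U50736_s_at) rose 12.3-fold in diabetic muscle (log2 change 3.62 ± 0.53, SE, n = 5 per group, adjusted p = 0.00162), from 9.98 ± 0.42 to 13.60 ± 1.04 (mean log2 signal ± SD). Spp1 (M14656_at), the secreted matrix protein osteopontin, rose 8.43-fold (3.08 ± 0.51, adjusted p = 0.00374), and the macrophage enzyme lysozyme, Lyz2 (rc_AA892775_at), rose 5.99-fold (2.58 ± 0.45, adjusted p = 0.00505). The lipid droplet protein Cidea (rc_AA800243_at) rose 4.52-fold (2.18 ± 0.33, adjusted p = 0.00204) and Cpt1a (L07736_at), an enzyme that admits long-chain fatty acids to mitochondria, rose 3.46-fold (1.79 ± 0.36, adjusted p = 0.0143). The insulin-regulated glucose transporter Slc2a4 (D28561_s_at) was 2.24-fold lower (-1.16 ± 0.29, adjusted p = 0.045) and the insulin receptor substrate Irs1 (X58375_at) 2.61-fold lower (-1.38 ± 0.35, adjusted p = 0.0483).

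Among the other named genes with the largest rises were Coro1a, an actin-binding protein of leukocytes (10.4-fold, adjusted p = 0.0244), Camk2n1, an inhibitor of calmodulin-dependent kinase II (6.51-fold, adjusted p = 0.000587), Myh3, the embryonic myosin heavy chain (5.92-fold, adjusted p = 0.0155), and the matrix proteins Spock2 (5.39-fold, adjusted p = 0.00778) and Thbs4 (4.56-fold, adjusted p = 0.0146). Prkcb, S100a4 and Gstm2 completed the 12, with rises of 5.72-, 4.69- and 4.32-fold (adjusted p = 0.0456, 0.0348 and 0.0435). Coro1a and Camk2n1 lay under the array's 40th percentile in all 5 normal arrays and Spp1 in 4 of 5, so their folds rest on dim normal signals; with a larger pseudocount the log2 changes of Coro1a, Camk2n1, Spp1, Prkcb and Spock2 were 2.15, 1.61, 1.96, 1.28 and 1.65. The other Myh3 probe sets gave log2 changes of 0.34 (adjusted p = 0.675) and 4.14 (adjusted p = 0.00557). An unnamed probe set, M33648_at, chosen after its values were seen, had the smallest adjusted p of the comparison (1.83e-05) and rose 16.3-fold (4.03 ± 0.40). It too lay under the 40th percentile in all 5 normal arrays, and its log2 change was 2.26 with a larger pseudocount.

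The largest fall among the named genes was that of Alas1 (J03190_at), the first enzyme of heme synthesis, which was 4.80-fold lower (-2.26 ± 0.42, adjusted p = 0.00838). Amhr2, Synpo, Fgd4, Slc41a3, Smad3, a transducer of TGF-beta signals, and Cmss1 fell by 2.00, 1.97, 1.93, 1.91, 1.90 and 1.75 on the log2 scale. The long-chain acyl-CoA synthetase Acsl6 fell by 1.66, Prss1 by 1.58, and Phkg1, the catalytic subunit of muscle phosphorylase kinase, by 1.48. P2rx6 and Lnpep, an aminopeptidase that travels with the insulin-regulated glucose transporter, fell by 1.47 and 1.46. The adjusted p of these 11 genes ran from 0.0222 to 0.0496. Each of these 24 genes showed its direction in 5 of 5 diabetic arrays against the normal mean. Genes chosen for their change in the same arrays tend to do so, and such counts, here and below, are no separate support. The values of the 2 groups did not overlap for 9 of the 12 risen and 9 of the 12 fallen genes.

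**Figure D2:**
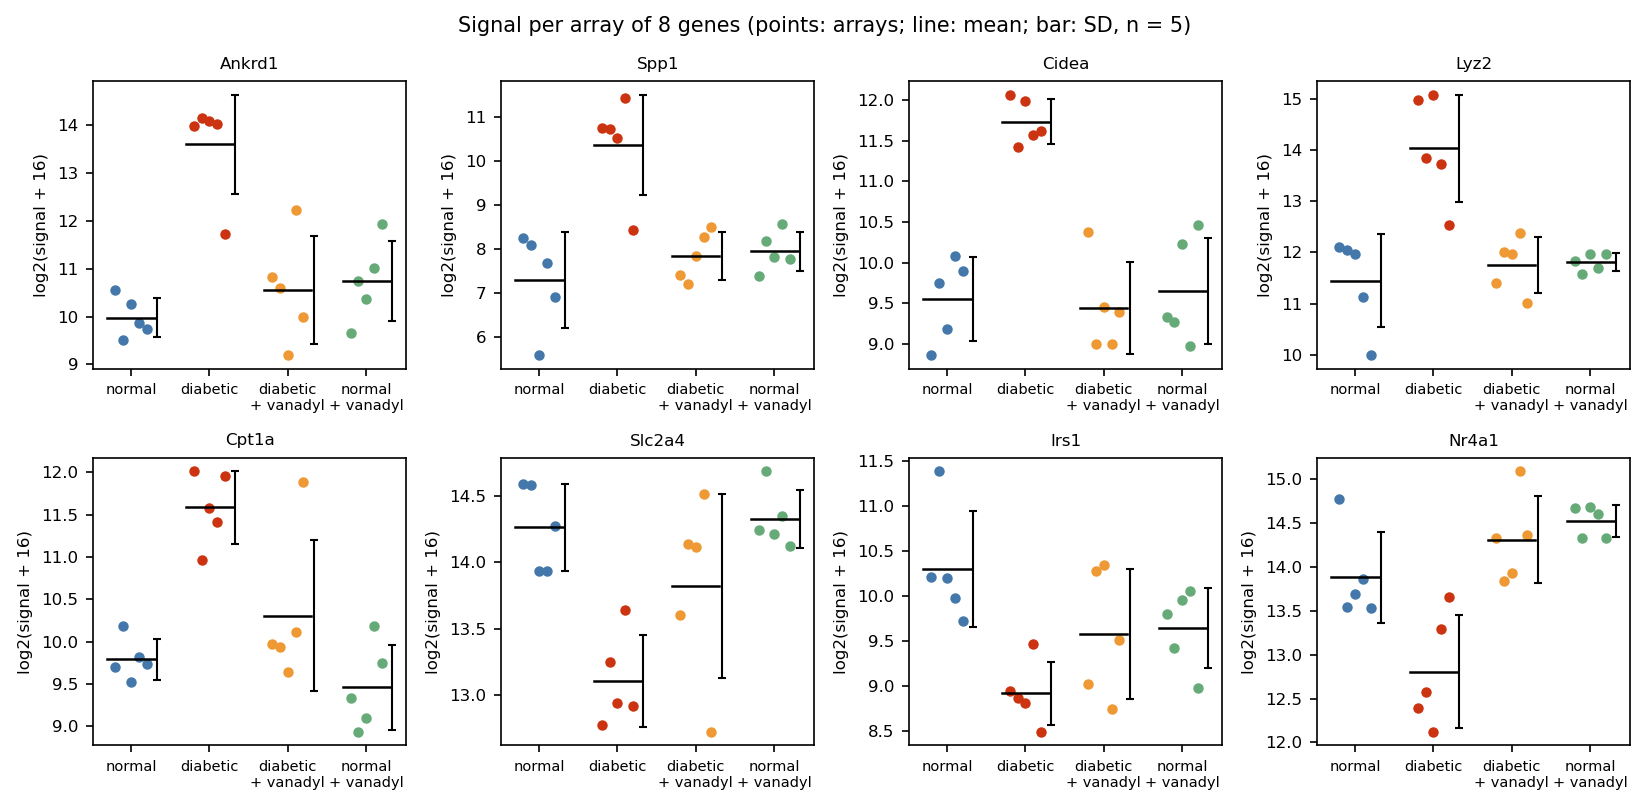
Log2(signal + 16) of 8 genes in each array, by group; points are arrays, lines are means and bars are SD (n = 5). Ankrd1, Spp1, Cidea and Lyz2 rose in diabetic muscle and fell with treatment, Slc2a4 and Irs1 were lower in diabetic than in normal muscle, and the Cpt1a signal of treated diabetic replicate 5 was 11.88.

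Immune cell markers rose as a list (22 genes measured; adjusted p = 9.8e-07, and adjusted p = 0.230 with an estimated correlation). Over all genes tested 6 members rose and 0 fell, and 16 did not pass. When adjusted over the list alone, 9 rose. They included the inhibitory Fc receptor Fcgr2b (1.66 ± 0.27, adjusted p = 0.00374), the lectin Lgals3 (1.49 ± 0.25, adjusted p = 0.00374), Lyz2 and the chemokine Ccl2 (1.48 ± 0.32, adjusted p = 0.0208). The list score was 1.49 or more in diabetic replicates 1 and 3, and 0.40, 0.58 and 0.21 in replicates 2, 4 and 5, where the SD among the normal arrays was 0.18 (n = 5). Adipocyte markers rose too (8 genes; adjusted p = 0.00934, and 0.190 as the adjusted p with an estimated correlation), with Cidea, the fatty acid carrier Fabp4 (1.86 ± 0.44, adjusted p = 0.0344) and the lipase Lipe (1.09 ± 0.27, adjusted p = 0.0446) risen and 5 not past the test. Once adjusted over the list alone, 4 rose. Leptin, the adipocyte marker with the highest mean signal in normal muscle, had a log2 change of -0.33 (adjusted p = 0.522).

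Genes of energy metabolism fell as lists. All 14 measured genes of the tricarboxylic acid cycle and pyruvate entry list had negative changes (mean -0.73, adjusted p = 9.8e-07, and adjusted p = 0.190 with an estimated correlation). The list also holds the aminotransferases Got1 and Got2 and the cytosolic malate dehydrogenase Mdh1. Mdh2, a malate dehydrogenase, fell by 1.22 (adjusted p = 0.0197) and 13 did not pass over all genes tested. If adjusted over the list alone, 7 fell, and Dlat and Pdhb of the pyruvate dehydrogenase complex had values of -1.18 and -0.94. The list score was -1.01 and -1.09 in diabetic replicates 1 and 3 and between -0.54 and -0.48 in the other 3. These 2 arrays, which also had the highest immune scores, had the highest 3'/5' ratios of their group (log2 beta-actin 2.30 and 2.52 against 0.93 to 1.97, Gapdh 0.90 and 1.11 against 0.21 to 0.51). Oxidative phosphorylation fell (35 genes, 32 negative, mean -0.46; adjusted p = 8.78e-06, and adjusted p = 0.466 with an estimated correlation), with cytochrome c1, Cyc1, past the test (-1.09, adjusted p = 0.0433) and 6 genes adjusted over the list alone. Slc25a3 and Cox5b had values of -0.77 and -0.92. This list did not pass once the 3 arrays of high Gapdh ratio were left out. The glycolysis and glycogen list fell (26 genes, mean -0.40; adjusted p = 0.0451, and adjusted p = 0.230 with an estimated correlation), with Phkg1 and Slc2a4 fallen, 0 risen and 24 not past. With p adjusted over the list alone, 3 fell and 2 rose, among them the phosphofructokinase Pfkp (1.07). Its call ended when normal replicate 2, 4 or 5 or diabetic replicate 2 or 5 was left out, with no filter and with both 3'/5' ratios as covariates.

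Ribosomal protein genes rose as a list (41 genes, 36 positive, mean 0.38; adjusted p = 2.53e-05, and adjusted p = 0.408 with an estimated correlation), although 0 members passed limma's test over all genes or adjusted over the list alone. Rpl14 and Rpl41 had the smallest p, with log2 values of 0.75 and 1.11. With fry, which tests the direction of a list's own genes, the tricarboxylic acid cycle (adjusted p = 0.00742), adipocyte (0.00742) and immune (0.0281) lists passed and the other 3 did not.

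Fatty acid uptake and oxidation did not pass as a list (28 genes, adjusted p = 0.251), but Cpt1a and the dienoyl-CoA reductase Decr1 (1.53 ± 0.31, adjusted p = 0.0148) rose and Acsl6 fell. When adjusted over the list alone, 4 rose and 1 fell. In the PPAR-linked fasting genes (15 genes, adjusted p = 0.129), Cpt1a and the lipid droplet protein Plin2 (1.28 ± 0.30, adjusted p = 0.0348) rose, and adjusted over the list alone these were 2. Pdk4, the kinase that shuts pyruvate dehydrogenase, had a value of 1.16 ± 1.16 (adjusted p = 0.64), Ucp3 of 0.37, Cpt1b of 0.49, Lpl of 0.83, Cd36 of -0.10 and Fabp3 of 0.20. In insulin and IGF signalling (36 genes, adjusted p = 0.474), Irs1 and the receptor-binding adaptor Grb14 (-1.19 ± 0.25, adjusted p = 0.0159) fell and 34 did not pass. Once adjusted over the list alone, 3 fell and 2 rose. Insr had a value of 0.06, Hk2 of 0.40, Actb of 0.62 and the desaturase Scd of -2.59 ± 1.00 (adjusted p = 0.187). In the extracellular matrix list (30 genes, adjusted p = 0.411), Spp1 and the collagen cross-linking enzyme Lox (1.36 ± 0.27, adjusted p = 0.0146) rose and Col15a1 (-1.32 ± 0.31, adjusted p = 0.0348) fell. If adjusted over the list alone, 2 rose and 2 fell. In the antioxidant and metal response list (36 genes, adjusted p = 0.155), Gstm2 rose. With p adjusted over the list alone, 3 rose and 2 fell.

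The other 11 lists did not pass: slow fibre (10 genes, adjusted p = 0.131) and fast fibre contractile genes (13, 0.0668), ubiquitin and proteasome (30, 0.510), heat shock and chaperones (26, 0.389), lipid and cholesterol synthesis (21, 0.991), neuromuscular junction and denervation (19, 0.734), and the markers of blood cells (6, 0.991), endothelium (12, 0.607), smooth muscle (8, 0.358), nerve and Schwann cells (10, 0.510) and mast cells (4, 0.317). Fabp4, which the endothelial list shares, was the only member of these past the test over all genes tested. Mean and median differed in sign for the lipid synthesis, neuromuscular, endothelial and nerve lists.

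By limma, 110 of 6027 probe sets passed in diabetic against normal muscle, 76 higher and 34 lower. At an unadjusted p under 0.05 there were 1007, where the mean with no effect is 301, and the median SE was 0.357. Since probe sets vary together, such counts can lie far above that mean. Regrouped arrays of treated diabetic and normal muscle reached 1613. The count past the adjusted threshold was 25 without diabetic replicate 1, 24 without replicate 3, 3 without both, 247 without normal replicate 1, and 53, 48 and 36 without normal replicates 2, 4 and 5. Ankrd1, Spp1, Camk2n1, Lyz2, Spock2, Cidea and Alas1 passed with any 1 array left out, whereas Slc2a4 and Irs1 each lost their call without 8 of the 10 arrays. The number of probe sets was 282 with the Gapdh ratio as a covariate, 32 with both ratios, and 464 without the 3 arrays of high Gapdh ratio. In the fit without these arrays, the mean log2 beta-actin ratio was 0.59 in normal and 1.75 in diabetic muscle. Its values did not overlap between the groups, so 3' bias cannot be told apart from diabetes for the 464. With the Gapdh ratio added to that fit, the count was 50.

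Diabetic muscle with vanadyl sulfate was set against untreated diabetic muscle to ask what the treatment changed in diabetic rats. Ankrd1 was 8.19-fold lower in treated rats (log2 change -3.03 ± 0.53, SE, n = 5 per group, adjusted p = 0.0118) and Spp1 5.76-fold lower (-2.53 ± 0.51, adjusted p = 0.0281). Cidea was 4.88-fold lower (-2.29 ± 0.33, adjusted p = 0.00299) and Lyz2 4.85-fold lower (-2.28 ± 0.45, adjusted p = 0.0219). Fhl2 (rc_AA891527_at), a LIM-domain protein of striated muscle, was 9.81-fold lower (-3.29 ± 0.57, adjusted p = 0.0118), and its log2 change was -1.77 with a larger pseudocount. The unnamed M33648_at, chosen after its values were seen, had a change of -3.91 ± 0.40 (-2.23 with a larger pseudocount). Myh3, Esm1, a proteoglycan secreted by endothelium, Thbs4, Camk2n1 and the inositol monophosphatase Impa2 fell by 2.34, 2.08, 2.01, 1.92 and 1.85 on the log2 scale (adjusted p = 0.0471, 0.00299, 0.0409, 0.0158 and 0.0136). Only 3 genes rose: Adprs, an ADP-ribose hydrolase (3.83-fold, adjusted p = 0.0409), Nr4a1, a nuclear receptor induced early by many signals (2.84-fold, adjusted p = 0.036), and Ndufb9, a subunit of respiratory complex I (2.20-fold, adjusted p = 0.0409). All 13 showed their direction in 5 of 5 treated arrays, and the values of the 2 groups did not overlap for 7 of the 10 fallen and 2 of the 3 risen genes.

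Immune cell markers fell (22 genes, mean -0.79; adjusted p = 1.66e-07, and adjusted p = 0.230 with an estimated correlation). Lyz2, Fcgr2b (-1.32 ± 0.27, adjusted p = 0.0335) and Ccl2 (-1.48 ± 0.32, adjusted p = 0.0387) fell, 0 rose and 19 did not pass. When adjusted over the list alone, 9 fell. The score of this list in diabetic muscle was highest in replicates 1 and 3. Slow fibre contractile genes fell (10 genes, mean -1.15; adjusted p = 2.44e-06, and adjusted p = 0.230 with an estimated correlation), with the slow tropomyosin Tpm3 (-1.36 ± 0.30, adjusted p = 0.0471) past the test and 9 not. Once adjusted over the list alone, 7 fell. The list score of treated diabetic replicates 1 and 3 was 0.41 and 0.00018, and that of replicates 2, 4 and 5 was -1.46, -0.77 and -1.76. The muscle LIM protein Csrp3, calsequestrin Casq2 and the slow troponin Tnni1 had values of -1.81, -1.70 and -1.73. Fast fibre contractile genes rose as a list (13 genes, mean 0.41; adjusted p = 0.0292, and adjusted p = 0.586 with an estimated correlation), with 0 members past limma's test either way. Myh1 and parvalbumin, Pvalb, had values of 1.04 and 0.93. The list's call ended without diabetic replicate 4 or 5 or treated diabetic replicate 1 or 3, under quantile normalization and with the 3'/5' ratios as covariates.

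Oxidative phosphorylation genes rose (35 genes, 32 positive, mean 0.58; adjusted p = 2.79e-08, and adjusted p = 0.301 with an estimated correlation). None passed over all genes tested by limma, whose test gave 0 here. If adjusted over the list alone, 13 rose, and Atp5pb and Cox5a had values of 0.83 and 1.29. The tricarboxylic acid cycle list rose (14 genes, mean 0.51; adjusted p = 0.000282, and adjusted p = 0.230 with an estimated correlation), with 5 risen adjusted over the list alone and 0 over all genes. Got1, Pdhb and Mdh2 had values of 0.97, 0.79 and 0.76. This call ended when the probe sets of a gene were averaged. PPAR-linked fasting genes fell (15 genes, mean -0.74; adjusted p = 0.00365, and adjusted p = 0.190 with an estimated correlation), with 0 past over all genes and 3 fallen adjusted over the list alone. Plin2 had a value of -1.21 ± 0.30, Cpt1a of -1.28 ± 0.36, Pdk4 of -3.38 ± 1.16 (adjusted p = 0.178) and Ucp3 of -1.64 ± 0.66. Fatty acid uptake and oxidation fell (28 genes, mean -0.34; adjusted p = 0.0119, and adjusted p = 0.340 with an estimated correlation), with 2 fallen and 1 risen adjusted over the list alone and 0 over all genes. Decr1 had a value of -1.31 (adjusted p = 0.065). The antioxidant and metal response list fell (36 genes, mean -0.33; adjusted p = 0.0147, and adjusted p = 0.230 with an estimated correlation), with 1 fallen adjusted over the list alone and 0 over all genes. Of the metallothioneins planned for this list only Mt3 was tested, so it measured little of a metal response. The thioredoxin-binding protein Txnip had a value of -0.81 and Gstm5 of -1.72. Both of these calls ended without diabetic replicate 5. By fry, the PPAR-linked (adjusted p = 0.0224), tricarboxylic acid cycle (0.0230), immune (0.0383) and oxidative phosphorylation (0.0428) lists passed.

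Slc2a4 had a value of 0.72 ± 0.29 (adjusted p = 0.238), Irs1 of 0.66 ± 0.35 (adjusted p = 0.355), Hk2 of 1.03, Scd of 0.63, Cpt1b of -0.82, Cd36 of -1.36, Actb of -1.81, Lpl of -0.07, Insr of -0.17 and Fabp3 of 0.02. Lists that did not pass were extracellular matrix (adjusted p = 0.0668; Spp1 fell), adipocyte (0.131; Cidea fell) and smooth muscle markers (0.129), glycolysis and glycogen (0.224), neuromuscular junction (0.362), mast cell markers (0.438), ribosomal proteins (0.443), heat shock (0.773), endothelial markers (0.804), blood cell markers (0.916), insulin and IGF signalling (0.943), lipid synthesis (0.944), nerve and Schwann cell markers (0.991) and ubiquitin and proteasome (0.991).

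By limma, 30 probe sets passed in treated against untreated diabetic muscle, 3 higher and 27 lower, and 985 had an unadjusted p under 0.05. The count was 13, 19, 10 and 17 without diabetic replicates 1, 2, 3 and 4 and 20, 54 and 17 without treated diabetic replicates 1, 2 and 3, and 1 without diabetic replicates 1 and 3 together. Fhl2, Ankrd1, Cidea, Esm1 and Impa2 passed with any 1 array left out.

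Whether treatment moved back what diabetes changed was read from the probe sets past the threshold in both comparisons. There were 21, from 15 genes, all risen in diabetic and fallen in treated diabetic muscle, and 0 went the same way in both. They included Ankrd1, Spp1, Myh3, Lyz2, Cidea, Thbs4, Esm1, Camk2n1, Impa2 and Lyve1, a hyaluronan receptor of lymphatic endothelium, which rose by 1.71 ± 0.32 (adjusted p = 0.00889) and fell by 1.83 (adjusted p = 0.0118). Against normal muscle, the treated values of these 10 genes differed by -0.15 to 0.79 on the log2 scale, with adjusted p from 0.372 to 0.897. The genes were chosen for passing both comparisons in opposite directions, which favours treated values near normal. These p-values therefore do not show a return to normal. The 76 risen probe sets had median log2 changes of 1.73 with diabetes, -1.22 with treatment and 0.59 for treated diabetic against normal muscle, and the 34 fallen ones -1.46, 0.84 and -0.52.

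Both comparisons use the same diabetic arrays, so opposite signs arise with no effect at all. Of the 110 probe sets changed by diabetes, 109 (99.1%) had the opposite sign with treatment, where 100 simulations with no treatment effect gave 62.3% on average. The simulated diabetes effect was the observed change of the called probe sets. That change already holds noise of the shared arrays, so the simulated share and count can be too low. Those simulations gave 0 probe sets past both thresholds, and independent lists would share 0.340 risen and then fallen and 0.0169 fallen and then risen. Over all tested probe sets the correlation of the 2 sets of changes was -0.55 and the covariance -0.237, against -0.50 and -0.109 in simulations with no effect, a difference in covariance of -0.128. With the diabetic arrays divided between the comparisons in 20 ways, 1 to 7 probe sets (mean 1.75) passed both (35 over the 20 divisions, where independent lists give 0.345), 94.1% on average had the opposite sign, and the mean covariance was -0.163. The divisions reuse the same arrays, so their counts are not independent of each other. The 35 were 7 distinct probe sets, of which M33648_at passed both in all 20 divisions. The count of 21 was 9 without diabetic replicate 1, 13, 7 and 11 without replicates 2, 3 and 4, and 1 without replicates 1 and 3 together. It was 11 and 12 without treated diabetic replicate 3 and normal replicate 5; treated diabetic replicate 1 and the other arrays left it between 14 and 26.

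Normal muscle with vanadyl sulfate was compared with untreated normal muscle to see the treatment's effect without diabetes. Few genes moved: the scaffold protein Gipc1 (AF089817_i_at) rose 2.92-fold (log2 change 1.55 ± 0.25, SE, n = 5 per group, adjusted p = 0.0326) and the tyrosine kinase Fyn (rc_AI009191_at) 2.37-fold (1.24 ± 0.23, adjusted p = 0.0497). Other Gipc1 probe sets gave 0.09 and 0.30. The remaining 2 called probe sets are unnamed and were chosen after their values were seen: rc_AA944177_at rose 3.17-fold (adjusted p = 0.0326) and rc_AA859832_at 2.49-fold (adjusted p = 0.0497). All 4 were higher in 5 of 5 treated arrays. Pros1, Notch1 and Rbm39 had the next smallest p, with log2 values of 1.16, 0.94 and 1.36 (adjusted p = 0.136, 0.184 and 0.184).

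With the preset correlation, lists of muscle fuel and contraction lay lower relative to the other genes, and 0 lists passed with an estimated correlation. The median of all probe sets was itself 0.18 higher in treated normal muscle, and 0.015 and -0.02 after quantile normalization and median centring. Oxidative phosphorylation fell (35 genes, 32 negative, mean -0.28; adjusted p = 1.91e-08, and adjusted p = 0.292 with an estimated correlation), with Slc25a3 at -0.55 and Cox6b1 at -0.66. Fast fibre genes fell (13 genes, mean -0.47; adjusted p = 1.98e-06, and adjusted p = 0.230 with an estimated correlation), with the myosins Myh2 at -0.67 and Myh4 at -0.71. Slow fibre genes fell (10 genes, mean -0.66; adjusted p = 7.4e-05, and adjusted p = 0.291 with an estimated correlation), with Tnni1 at -1.60 and Myl3 at -0.99. Fatty acid uptake and oxidation fell (28 genes, mean -0.20, adjusted p = 9.64e-06, and adjusted p = 0.190 with an estimated correlation), with the carnitine carrier Slc25a20 at -0.85 and Fabp3 at -1.13. The list score among the normal arrays had an SD of 0.34 for oxidative phosphorylation, 0.56 for fast fibre and 0.35 for fatty acid genes. Each of these SDs exceeded the size of the list's mean change, unlike that of the slow fibre genes (0.21). The tricarboxylic acid cycle (14 genes, mean -0.21, adjusted p = 0.00035, and adjusted p = 0.237 with an estimated correlation, with Mdh1 -0.83, Suclg1 -0.57), PPAR-linked (15 genes, mean -0.22, adjusted p = 0.0198, and adjusted p = 0.213 with an estimated correlation, with Slc25a20 -0.85, Fabp3 -1.13) and glycolysis lists (26 genes, 15 negative, mean -0.07, adjusted p = 0.0224, and adjusted p = 0.230 with an estimated correlation, with Slc2a1 1.06, Pgam2 -0.84) lay lower than the other genes as well. In these 7 lists 0 members passed limma's test, over all genes or adjusted over the list alone, and 0 lists passed by fry. Quantile normalization ended the calls of 5 of them and left slow fibre and fatty acid genes. The PPAR-linked call also ended without normal replicate 2 or 5, and the glycolysis call without normal replicate 2 or 4 or treated normal replicate 5. The value of Insr was 0.86, of Irs1 -0.66, of Slc2a4 0.06 and of Cpt1a -0.34.

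By limma, 4 probe sets passed in treated against untreated normal muscle, all higher, and 556 had an unadjusted p under 0.05. The count was 0 under quantile normalization or median centring, 0 without normal replicate 2 or 5 or treated normal replicate 1, 2, 3 or 5, 1 without normal replicate 3 and 2 without treated normal replicate 4.

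What still set treated diabetic muscle apart from untreated normal muscle was the fourth question. The genes with the smallest p were the chaperone Hspa2 (log2 value -2.41 ± 0.42, SE, n = 5 per group, adjusted p = 0.0887), Spock2 (2.18 ± 0.44, adjusted p = 0.235), Notch1 (1.01 ± 0.21, adjusted p = 0.256), Tbxa2r (1.76, adjusted p = 0.27) and Vps26a (-1.26, adjusted p = 0.27), each with this direction in 5 of 5 treated arrays. Ribosomal protein genes were higher as a list (41 genes, 32 positive, mean 0.36; adjusted p = 0.000303, and adjusted p = 0.496 with an estimated correlation), with Rpl41 at 1.26 and Rps6 at 1.09. Quantile normalization ended this call. Slow fibre genes were lower (10 genes, 9 negative, mean -0.71; adjusted p = 0.00146, and adjusted p = 0.388 with an estimated correlation), with Tnni1 at -1.40, Atp2a2 at -0.94 and Myl2 at -1.67. In both lists 0 members passed limma's test, also when adjusted over the list alone, and 0 lists passed by fry. Slc2a4 had a value of -0.45, Irs1 of -0.72, Hk2 of 1.43, Scd of -1.96, Pdk4 of -2.22 and Cpt1a of 0.51. By limma 0 of 6027 probe sets passed and 770 had an unadjusted p under 0.05. The count was 1 with array weights, 2 without normal replicate 3, 3 without treated diabetic replicate 2, and 359 without the 3 arrays of high Gapdh ratio. In the 3 normal and 4 treated diabetic arrays that stayed in that fit, the mean log2 Gapdh ratio was 0.064 and 0.75.

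**Figure D3:**
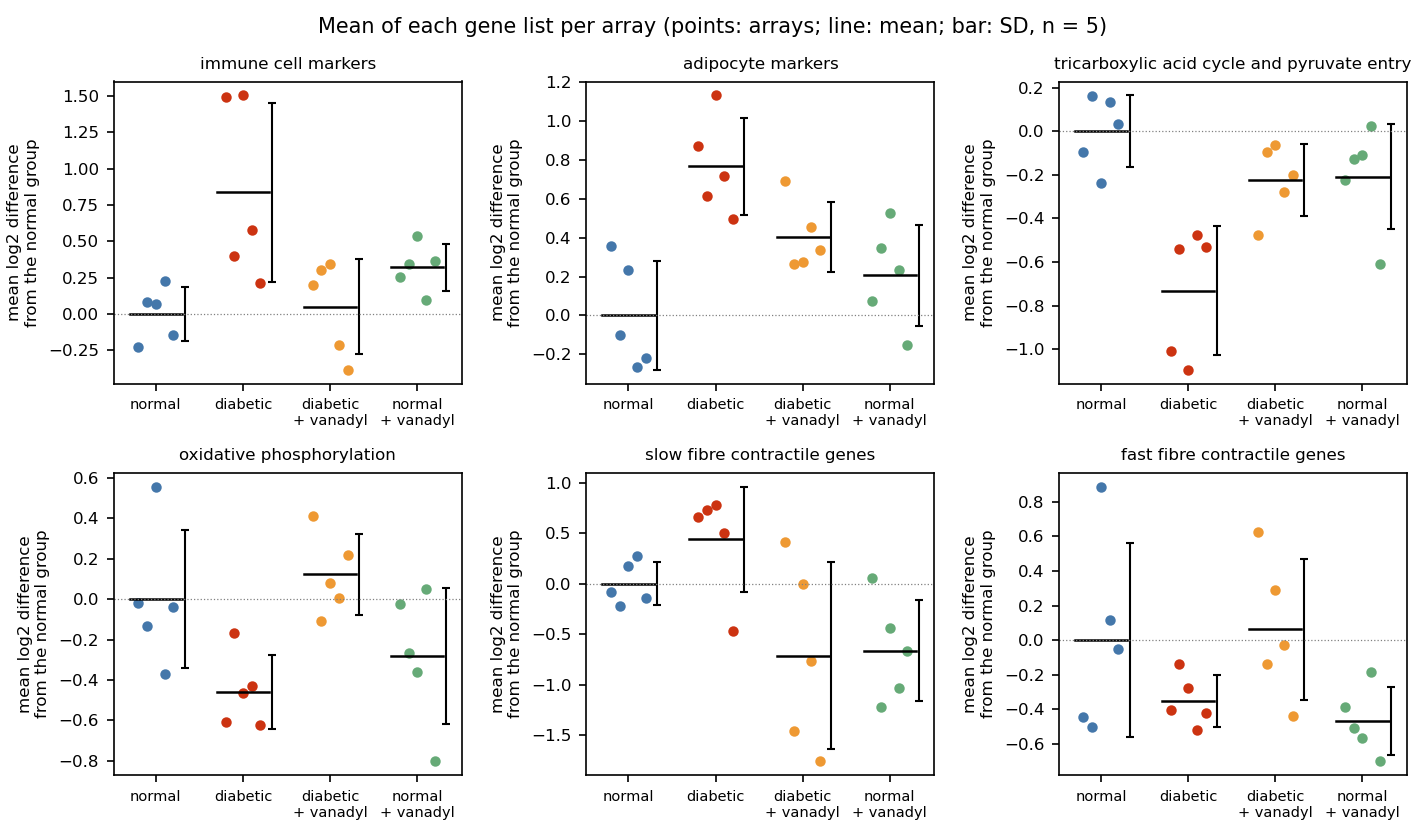
Mean log2 difference from the normal group over the genes of 6 lists in each array, by group; points are arrays, lines are means and bars are SD (n = 5). The immune score was 1.49 or more in diabetic replicates 1 and 3 and at most 0.58 in the other diabetic arrays, and the slow fibre score averaged -0.71 in treated diabetic and -0.66 in treated normal muscle.

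The interaction tests whether treatment acted differently in diabetic and in normal rats. The treatment difference of Ankrd1 was lower in diabetic than in normal rats, with an interaction of -3.80 ± 0.75 on the log2 scale (SE, n = 5 per group, adjusted p = 0.0442); its value was -3.03 in diabetic and 0.76 in normal rats. Alox5ap (X52196cds_at), which helps make leukotrienes, had an interaction of -2.98 ± 0.55 (adjusted p = 0.0347), from -1.49 in diabetic and 1.49 in normal rats. The interactions of Cidea (-2.39, adjusted p = 0.0442), Lyve1 (-2.35, adjusted p = 0.0434) and Fcgr2b (-2.16, adjusted p = 0.0315) came from negative values in diabetic rats and values of 0.10, 0.52 and 0.83 in normal rats. Chosen after their values were seen, the complement inhibitor Serping1 (-1.75) and 1 Lox probe set, S66184_s_at (-2.93), passed too (adjusted p = 0.0442 each), while the Lox probe set of highest signal had a value of -1.52. The other 3 called probe sets have no single gene name: M33648_at (-4.26 ± 0.57, adjusted p = 0.0019), rc_AA859832_at (-1.98) and rc_AI176456_at (-5.47), which the annotation pairs with several symbols. Slc2a4 had a value of 0.66, Irs1 of 1.32, Pdk4 of -3.06 and Cpt1a of -0.94.

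Oxidative phosphorylation rose with treatment in diabetic relative to normal rats (35 genes, mean 0.86; adjusted p = 1.32e-14, and adjusted p = 0.230 with an estimated correlation), with 17 risen adjusted over the list alone, among them Slc25a3 (1.26) and Cox6b1 (1.57). The tricarboxylic acid cycle list rose (14 genes, mean 0.72; adjusted p = 9.8e-07, and adjusted p = 0.190 with an estimated correlation; 6 adjusted over the list alone), with Mdh1 at 1.67 and Mdh2 at 1.28. Fast fibre genes (13 genes, mean 0.88; adjusted p = 3.41e-06, and adjusted p = 0.230 with an estimated correlation; 7 adjusted over the list alone), with Pvalb at 1.67 and Myh4 at 1.45, and glycolysis genes (26 genes, mean 0.28; adjusted p = 0.0175, and adjusted p = 0.230 with an estimated correlation; 2 adjusted over the list alone), with Pgam2 at 2.06 and Pkm at 1.24, rose too. Quantile normalization ended both calls. Immune cell markers fell (22 genes, mean -1.11; adjusted p = 1.78e-06, and adjusted p = 0.230 with an estimated correlation), with Fcgr2b past the test, 7 fallen adjusted over the list alone, and Lyz2 at -2.63. The antioxidant and metal response list fell (36 genes, mean -0.60; adjusted p = 0.0312, and adjusted p = 0.292 with an estimated correlation; 3 adjusted over the list alone), with Gstm2 at -2.88 and Gstm5 at -2.75. Its call ended in 10 of 33 alternatives, among them those without normal replicate 3 or 4, diabetic replicate 5, treated diabetic replicate 5 or treated normal replicate 5. It also ended in every fit with a 3'/5' ratio as a covariate or without the 3 arrays of high Gapdh ratio. Apart from Fcgr2b, 0 members of these 6 lists passed over all genes tested. By fry the tricarboxylic acid cycle, oxidative phosphorylation, antioxidant and immune lists passed.

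By limma, 10 probe sets passed the interaction, all with negative values, and 800 had an unadjusted p under 0.05, with a median SE of 0.505. The count ran from 1 (without normal replicate 5, diabetic replicate 1, 3 or 4, treated diabetic replicate 3 or treated normal replicate 3) to 22 (without diabetic replicate 5), and was 3, 6, 2, 4 and 2 without normal replicates 2 and 4, treated diabetic replicate 1 and treated normal replicates 2 and 5. Only M33648_at passed in each of these fits.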

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

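The tests of 3' bias and of a larger share of all non-muscle cells (both forms) for the probe sets higher in diabetic muscle, of 3' bias for those moved back, of probe sets past both thresholds with no diabetic array shared, of leaving out any 3 arrays, and of splits by the count at an unadjusted p under 0.05 were chosen after the results were seen.

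In diabetic muscle 76 probe sets were higher, immune markers among them, and 34 lower; the excess of higher ones held with both 3'/5' ratios as covariates (23 against 9) but shrank with the Gapdh ratio (147 against 135) and turned without the 3 arrays of high Gapdh ratio (225 against 239) or with that fit and the Gapdh ratio (24 against 26), so 3' bias stays open for the excess. Unequal 3' bias was argued against as the whole cause of the rise of the 76: with both 3'/5' ratios as covariates the median log2 change of the 76 was 1.56 (SE 0.388) against 1.73 (SE 0.356) before, all 76 kept their direction, and 21 kept their call, the others losing it as changes shrank and the SE grew. A larger share of every non-muscle cell type alike was argued against, since the immune score minus the mean of the endothelial, smooth muscle, nerve and blood scores was 0.71 higher in diabetic muscle (exact p = 0.00794, the smallest possible), and 0.55 higher (exact p = 0.0317) with the adipocyte and mast cell scores, which were 0.77 and 0.42 higher themselves, in that mean. More immune cells may be a source (list adjusted p = 9.8e-07, and 0.230 with an estimated correlation; 18 of its 22 genes lay above the 40th percentile in at least 3 normal arrays and 0 are in another list): its most abundant members went from 12.85 to 13.99 (RT1-Da), 11.64 to 13.21 (C1qb, adjusted p = 0.0633) and 11.63 to 13.32 (Cd74, adjusted p = 0.106). What stays open is how far diabetic replicates 1 and 3, which had the highest 3'/5' ratios of their group, carry the pattern, because without both the median change was 1.58 (SE 0.414) and 3 probe sets passed, and the gene list immune cell markers, diabetic against normal, passed with diabetic replicates 1 and 3 left out at a smaller size (mean difference from the other genes 0.37, against 0.84 with all arrays, adjusted p = 0.00196, where its alternatives ran from 6.11e-09 to 0.230).

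Of the probe sets changed by diabetes, 21 moved back with treatment. Unequal 3' bias was argued against as the whole cause of the move of the 76 risen probe sets, whose median was -1.19 (SE 0.349) with both ratios as covariates and -1.22 (SE 0.356) without. That median was -1.05 without the 3 arrays of high Gapdh ratio and with the Gapdh ratio and -0.88 (SE 0.414) without diabetic replicates 1 and 3, so a part stays open. Of the 21, 11 stayed past both thresholds with both covariates and 9 without the 3 arrays and with the Gapdh ratio. The changes with diabetes had a larger SE there (0.388 and 0.421 against 0.356). Changes shrank too: the median with diabetes went from 1.73 to 1.56 with both covariates, and the median with treatment to -1.05 in the other fit. The sharing of the diabetic arrays by both comparisons was argued against as the whole cause: with these arrays divided in 20 ways so that none was shared, 20 divisions held a probe set past both thresholds in opposite directions, 35 in all where independent lists give 0.345: M33648_at in 20, Cidea in 6, Esm1 in 5, and Ankrd1, Camk2n1, rc_AI176456_at and, outside the 21, Lox S66184_s_at in 1 each. The divisions reuse the same arrays, so these counts are not independent of each other. The probe sets with 1 each all passed in the same division, which set only diabetic replicates 1 and 3 against treated muscle. Their single pass thus rests on those 2 arrays. For Ankrd1, Camk2n1, rc_AI176456_at and the 15 of the 21 that passed in no division, sharing cannot be told apart from a treatment effect. Simulations with shared arrays and no treatment effect gave 0 probe sets past both thresholds and 62.3% opposite signs (highest 90.2%) against 99.1%. However, they shuffle the arrays' deviations over the groups and so do not keep diabetic replicates 1 and 3 together in the diabetic group. These simulations also took the observed changes of the called probe sets as the diabetes effect, which can make both values too low. The median move of the risen probe sets was negative in all 20 divisions (median -1.97), but it was -0.41 and -0.45 in those that used diabetic replicates 1 and 3, or 1, 3 and 5, for the diabetic comparison and called 222 and 167 probe sets, which keeps this open, as does an effect of vanadyl sulfate.

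Without the 3 arrays of high Gapdh ratio, 359 probe sets (134 higher, 225 lower) separated treated diabetic from normal muscle, against 0 with all arrays. Leaving out just any 3 arrays was argued against: 0 of 45 other sets without both normal replicates 1 and 3 gave as many (highest 112), and the 5 sets holding both gave 316 to 902. Unequal 3' bias among the arrays left cannot be told apart from a group difference for these probe sets. With the Gapdh ratio as a covariate their median size was 1.17 (SE 0.455) against 1.86 (SE 0.467), between what either would give, and 0 kept their call because the changes shrank. The remaining arrays differed in mean beta-actin ratio, 0.59 in normal and 1.80 in treated diabetic muscle, and a difference between the groups stays open.

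Chance was argued against by 100 splits for diabetic against normal muscle (1 split, the real one, gave as many, with 110 against a highest other of 104), for treated against untreated diabetic muscle (1, with 30 against 5) and for the interaction (1, with 10 against 3). These counts depended on single arrays: with 1 array left out they were as low as 24, 10 and 1 in the same order. The split with 104 set normal replicates 1 and 3 and diabetic replicates 1, 3 and 5 against the others, the split with the largest difference in both ratios (Gapdh 1.67 against 0.14, beta-actin 2.30 against 0.75). A division along the 3'/5' ratios thus came near the real count of 110. Chance cannot be excluded for treated against untreated normal muscle (5 splits gave as many; 4 against 53). For treated diabetic against normal muscle the real count by limma was 0 (highest other 753), so all 100 splits reach it and the count decides nothing; at an unadjusted p under 0.05, 19 of the 100 splits gave as many as the real 770 (highest other 1613), so chance cannot be excluded there. The split with 53 set normal replicates 1 and 3 and treated normal replicates 1, 3 and 4 apart (Gapdh 1.35 against 0.042), and the split with 753 set normal replicates 1 and 3 and treated diabetic replicates 1, 3 and 5 apart (Gapdh 2.42 against 0.16). Each lay among the 5 splits of its comparison with the largest differences in both ratios, and such counts point to a structure of the samples that follows the 3'/5' ratio.

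In 22 of 240 groups of 5 values of named genes, 1 array stood far from the other 4, where chance gives about 1 in 20, or 12. In normal muscle these were Coro1a in replicate 2 (log2 signal 7.879, others 6.356 to 6.717), Cmss1 in replicate 2 (12.39, others 10.54 to 10.99), Rbm39 in replicate 2 (8.946), Nr4a1 in replicate 1 (14.78, others 13.53 to 13.87), Esm1 in replicate 5 (9.259) and Lyve1 in replicate 3 (9.643, others 8.291 to 8.459). In diabetic muscle they were Ankrd1 in replicate 5 (11.73, others 13.99 to 14.15), Fhl2 in replicate 5 (7.924, others 9.919 to 10.36), Impa2 in replicate 5 (12.11) and Notch1 in replicate 1 (11.15). In treated diabetic muscle they were Spock2 (11.4) and Cmss1 (8.695) in replicate 4, Smad3 (7.983) and Insr (7.451) in replicate 3, Rbm39 (8.936) and Hspa2 (7.732, others 5.385 to 5.84) in replicate 2, and Cpt1a in replicate 5 (11.88, others 9.638 to 10.11). In treated normal muscle they were Prkcb in replicate 4 (6.752), Fgd4 (7.931) and Impa2 (8.45) in replicate 5, Fhl2 in replicate 1 (9.564, others 6.013 to 7.025) and the probe set rc_AI176456_at in replicate 5 (15.42, others 10.87 to 11.97). The 10 brightest probe sets held 12.15% of the signal in normal replicate 3 and 3.151% to 4.625% in the other normal arrays, 1 such case among 20 groups of array measures.

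The treatment difference itself differed between diabetic and normal rats by the interaction test for 10 probe sets: M33648_at (-4.26), rc_AI176456_at (-5.467), Ankrd1 (-3.797), Alox5ap (-2.98), Lox S66184_s_at (-2.932), Cidea (-2.386), Lyve1 (-2.349), Fcgr2b (-2.159), rc_AA859832_at (-1.976) and Serping1 (-1.751).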

How the results depend on the processing

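The fits with a larger pseudocount, with the 3'/5' ratios as covariates, and without the 3 arrays of high Gapdh ratio or diabetic replicates 1 and 3 were chosen after the data were seen; where no cause is given below, the cause was not tested. Of 70 results of named genes past the threshold, 70 kept their direction under every alternative that gave them a value (39 compared), and 4 stayed past the threshold under each: Camk2n1 in diabetic against normal muscle, and M33648_at in that comparison, in treated against untreated diabetic muscle and in the interaction. Slc2a4 and Irs1 in diabetic against normal muscle had adjusted p from 0.0121 to 0.49 and from 0.0249 to 0.387. Counts of probe sets follow in the order higher/lower where brackets are given. With no filter, which adds dim probe sets to the tests, there were 62 (47/15) in diabetic against normal muscle, 19 (0/19) in treated against untreated diabetic muscle, 0 in treated against untreated normal muscle (556 at an unadjusted p under 0.05 in limma with the filter), 1 in the interaction and 12 moved back. With only the compared groups in the fit, which uses fewer samples, these were 71 (54/17), 11 (0/11), 0 for treated normal muscle, and 11 moved back. Array weights gave 515 (320/195), 112 (27/85), 19 (16/3) in treated normal muscle, 1 in treated diabetic against normal muscle, 40 (7/33) in the interaction and 59 moved back. A pseudocount of 1 gave 2 in treated normal muscle, and the larger pseudocount 50 in treated against untreated diabetic muscle and 35 moved back. Quantile normalization gave 0 in treated normal muscle, 1 in the interaction and 4 lists past the threshold in treated normal muscle; median centring gave 0 and 5 (2/3). A block for the replicate number gave 0 in treated normal muscle and 6 in the interaction, and same-number arrays correlated from -0.28 to 0.62 after group means were removed, with 8 of 30 closest to their own number, so the numbers were not used as pairs. The Gapdh ratio as a covariate gave 282 (147/135) in diabetic against normal muscle and 3 in the interaction, and both ratios 32 (23/9) and 1. Without the 3 arrays the counts were 464 (225/239) in diabetic against normal muscle, 2 in treated normal muscle, 359 (134/225) in treated diabetic against normal muscle and 1 in the interaction; with the Gapdh ratio added they were 50 (24/26), 46 (5/41) in treated against untreated diabetic muscle, 14 (4/10) in treated normal muscle, 17 (4/13) in the interaction and 10 moved back, with 4 lists in treated diabetic against normal muscle. Without diabetic replicates 1 and 3 they were 3 in diabetic against normal muscle, 1 in treated against untreated diabetic muscle, 1 in the interaction and 1 moved back. Leaving out 1 array at a time gave 24 to 247 in diabetic against normal muscle, 10 to 54 in treated against untreated diabetic muscle, 0 to 4 in treated normal muscle, 0 to 3 in treated diabetic against normal muscle, 1 to 22 in the interaction and 7 to 26 moved back; lists past the threshold were 5 to 7, 6 to 9, 5 to 8, 2 to 3 and 5 to 6 in the order of the comparisons. With an estimated correlation 0 lists passed in any of the 5 comparisons, against 6, 8, 7, 2 and 6 with the preset one; fry passed 3, 4, 0 and 0 in the first 4, and the mean over probe sets of a gene gave 5 lists in treated diabetic against normal muscle. The mean difference of the ribosomal list from the other genes changed sign from values not past the test: in treated normal muscle from -0.087 under quantile normalization (0.23, adjusted p = 0.000598), and in the interaction from 0.030 under quantile normalization (-0.49), the Gapdh covariate (-0.30), both covariates (-0.23), the fit without the 3 arrays (-0.28) and that fit with the Gapdh covariate (-0.28), with adjusted p from 7.21e-07 to 0.0354 there. Array signal over background limits the dim genes: Coro1a, Camk2n1 and M33648_at lay under the 40th percentile in all 5 normal arrays, and their log2 changes in diabetic against normal muscle were 3.38, 2.70 and 4.03, and 2.15, 1.61 and 2.26 with the larger pseudocount.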

Other observations

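No test of a hypothesis was added in this part, and the genes below were chosen after their values were seen. The neuromuscular junction and denervation list had 9 positive and 10 negative genes with diabetes (adjusted p = 0.734) and 9 positive and 10 negative with treatment (adjusted p = 0.362). Among its members, the cell-cycle inhibitor Cdkn1a had a log2 value of 1.57 in diabetic against normal muscle (adjusted p = 0.0887, n = 5 per group) and -0.58 with treatment (adjusted p = 0.547), the acetylcholine receptor subunit Chrnd 1.18 (adjusted p = 0.234) and -1.89 with treatment (adjusted p = 0.103), and Gadd45a 0.53 (adjusted p = 0.571) and -1.63 with treatment (adjusted p = 0.115). The immunoproteasome subunit Psmb8 had values of 0.93 (adjusted p = 0.333) and -1.42 (adjusted p = 0.169). Mvk, of cholesterol synthesis, had a value of 1.22 with treatment (adjusted p = 0.0816), with an interaction of 2.02 (adjusted p = 0.0716).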
